A study of Mus musculus with 6 samples.

How the data were processed

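The data are 6 Affymetrix Mouse 430 2.0 arrays, 3 of mock-treated and 3 of infected macrophages, grouped by the labels' titles, which also number the biological replicates. The authors deposited log2 values made with RMA (robust multi-array averaging), per the submitters' processing notes; its version is not given in the sources used here. RMA subtracts background, quantile-normalizes between arrays and summarises the probes of a probe set, so the arrays share nearly the same distribution: sorted values differed from their mean by at most 0.0782, and array medians lay between 5.50 and 5.52. Quantile normalization assumes that the total distribution is the same in both groups, so a shift of all genes could not be seen. RMA also compresses changes of dim probe sets. Scanner values and detection flags were not used here.

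The table holds 45101 probe sets, of which 64 are array controls, 34945 have a single gene symbol, 932 several and 9160 none in the platform annotation. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, which holds 34741 of the single-symbol probe sets and changed no symbol. Each gene was represented by its probe set with the highest mean over all 6 arrays, a choice blind to the groups, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets with several symbols or none were left out of the main test.

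Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values, two-sided, with Benjamini-Hochberg adjustment over all 18193 genes and a threshold of 0.05. The design held the group only. Gene lists (30 pathway lists and 8 lists of markers of other cell types) were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes and adjustment over the 38 lists. With the correlation estimated from these 6 arrays, 1 list passed. By limma's fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, 29 lists passed. Of 826 list entries 73 were not analysed here because no gene of the table matched. Some genes belong to more than 1 list, among them Arg1, Egr2, Pdcd1lg2 and Cd83, so the lists are not independent of each other. Reference lists of housekeeping, tissue-restricted and Y-linked genes served as checks. The 90th percentile of the mean levels of 49 tissue-restricted genes, 5.86, was taken as the background level. It stands in for detection flags. Of the housekeeping genes Polr2a rose by 0.44 and Hprt fell by 0.29 while 8 of 10 did not pass, and the 3 Y-linked genes lay below background in both groups.

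Genes named in the text followed a rule. The first part took the 15 largest rises and the 12 largest falls among genes past the threshold whose 3 infected arrays all lay on the same side of the 3 mock arrays and whose brighter group lay above background. Size was the difference of the means, not bounded at background. Provisional symbols would have been passed over, and none was met. The second part took up to 4 members with the largest change from each list, or the member with the largest change where none passed. Other list members are named as examples, chosen after their values were seen. The lists, the rule, the design and all alternatives but one, the division of the unfolded protein and ATF4 list, were fixed before the data were examined.

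The steps were tested on simulated data with the spread of these arrays and the same 18193 genes. Among 200 genes given a known change, limma recovered 46% at 0.5, 88% at 1, 98% at 2 and 100% at 4 on the log2 scale (50 genes each), and called 4 unchanged genes. In the real comparison 25.6% of genes were called, far more than were changed here. The adjusted p depends on that share, so these rates need not hold for the real comparison. Camera called 10 of 10 shifted lists and 0 of 20 unshifted lists, on simulated genes that vary independently. Alternatives changed the scaling, the treatment of dim and of several probe sets, the variance model, array weights, the replicate number as a block, the set test, and left out each array in turn.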

Results

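Transcript levels were measured in bone marrow-derived macrophages of female C57BL/6 mice, which are macrophages grown from marrow cells in medium with the growth factor M-CSF, here for 7 days. The cultures were either mock-treated or infected for 6 h with Toxoplasma gondii, an obligate intracellular protozoan parasite, of the Type I strain RH at a multiplicity of 2 parasites per cell. The labels describe biological triplicates, so 3 mock and 3 infected arrays were compared, and their number limits the precision of every value below. Levels are log2 expression values of Affymetrix Mouse 430 2.0 arrays, and 18193 genes were tested. The only comparison in the design is infected against mock, which asks how macrophage transcripts differ 6 h after infection. The arrays of a group correlated at 0.995 to 0.998 over all probe sets, and arrays of different groups at 0.980 to 0.985. The first principal component held 83.9% of the variance and separated the groups. Genes of the tissue-restricted list, which macrophages should not express, gave a background level of 5.86, their 90th percentile. A fold change is written as "at least" where the dimmer group lay under that level.

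In infected macrophages 2172 genes were higher and 2492 were lower than in mock-treated ones (limma, adjusted p under 0.05), and 502 and 295 of them changed at least 2-fold. By the differences of the group means, which were not bounded at the background level in these counts, 62 genes rose and 5 fell at least 8-fold. The transcription factor genes Egr3 (Entrez Gene 13655) and Egr1 (13653) were among the genes that rose most. Egr3 went from 3.80 ± 0.29 to 11.99 ± 0.23 (SD, n = 3), at least 70.0-fold higher, and Egr1 from 6.02 ± 0.22 to 13.12 ± 0.12, 137-fold higher, with adjusted p = 7.23e-10 and 2.49e-10. Socs2 (216233), a suppressor of cytokine signalling, rose from 4.22 ± 0.06 to 11.22 ± 0.01, at least 41.0-fold. Arg1 (11846), the cytosolic arginase, rose from 6.72 ± 0.43 to 13.08 ± 0.08, 82.1-fold. The other genes named by the rule for rises were Olr1, Egr2, Cish and Cd83, 43.3-, 41.6-, 32.2- and 30.2-fold higher, and 7 genes with a mock level under background, for which only a bound and no order can be given. These were Ccl24 (at least 39.9-fold), Arg2 (at least 32.1-fold), Pdcd1lg2 (at least 23.7-fold), Irf4 (at least 23.1-fold), Cxcl3 (at least 19.7-fold), Hbegf (at least 18.5-fold) and Ccl17 (at least 18.1-fold). Olr1, which encodes a receptor for oxidised low-density lipoprotein, rose from 6.98 ± 0.04 to 12.42 ± 0.11.

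The largest fall was that of Dusp6 (67603), a phosphatase that inactivates ERK kinases. Its level was 10.87 ± 0.19 in mock and 6.01 ± 0.28 in infected macrophages, 29.0-fold lower (adjusted p = 1.02e-08). Ccnd1 (12443), which encodes cyclin D1, fell from 12.76 ± 0.09 to 9.06 ± 0.07, 13.0-fold. The other genes named by the rule for falls were Prag1, Spred2, Spred1, Ubash3b, Slc39a14, Etv5, Cx3cr1 and Nfatc2, with log2 changes from -3.42 to -2.45, and Ccl12 and Spry2, which fell to below background, at least 6.61-fold and at least 5.72-fold. No probe set of these 27 genes changed in the opposite direction past the threshold. Several of them, among them Egr1, Arg1 and Dusp6, have a single probe set, so no other probe set could differ.

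**Figure D1:**
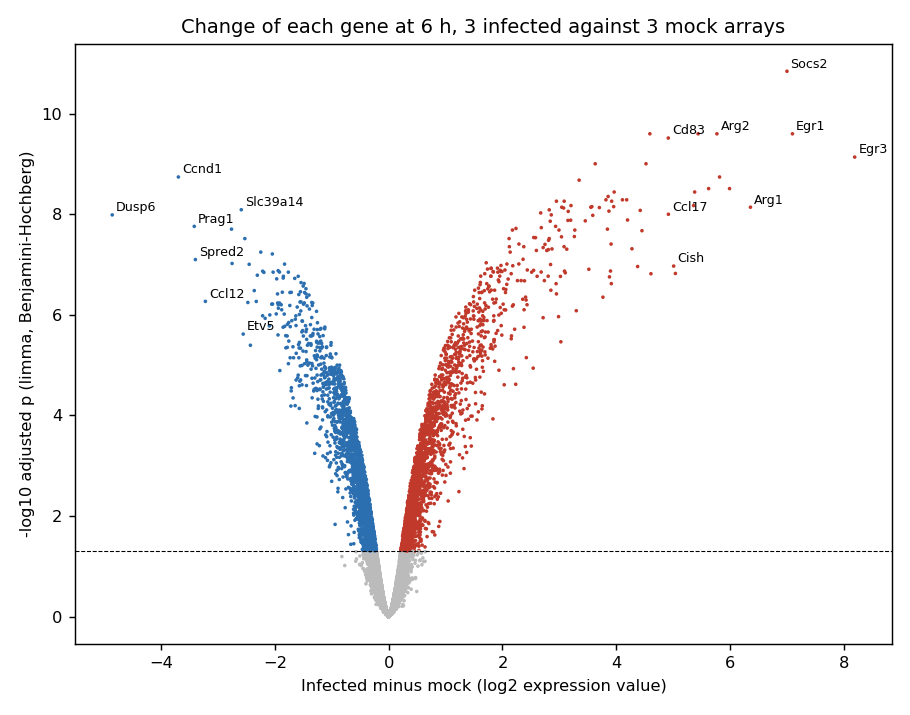
Each point is a gene, with the difference of the group means (infected minus mock, log2) on the horizontal axis and -log10 of the limma adjusted p on the vertical axis; red points were higher, blue points lower and grey points not past adjusted p = 0.05 (dashed line), and 15 of the largest changes are named. Differences of genes with a mean under the background level, such as 8.19 for Egr3, are drawn as measured and are not bounded, and Dusp6 lies lowest at -4.86.

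Genes of the immediate-early and MAP kinase feedback list moved both ways. Of its 38 measured members 22 rose, 10 fell and 6 did not pass the test (22 and 12 adjusted over the list alone; camera adjusted p = 1.11e-05, and adjusted p = 0.0535 with an estimated correlation). Besides Egr1, Egr2 and Egr3, the nuclear receptor genes Nr4a2 and Nr4a3 rose from below background, at least 17.4-fold and at least 9.83-fold, and Ier3 rose from 8.58 ± 0.18 to 12.28 ± 0.10 (SD, n = 3). The members that fell included Dusp6, Dusp4, Spry2, Spred1 and Spred2, of which the Sprouty and Spred proteins are known to restrain signalling from Ras to ERK, while Spry1 stood below background at 5.54 ± 0.04 and 5.58 ± 0.22. Other phosphatase genes of the list did not fall. Dusp2 rose from 6.31 ± 0.14 to 10.17 ± 0.11 and Dusp5 from 7.97 ± 0.18 to 9.63 ± 0.19, Dusp16 rose by 0.40 ± 0.09 (± SE), Dusp14 was higher below background, and Dusp1 stood at 11.98 ± 0.14 and 11.94 ± 0.02. Spred2 went from 10.19 ± 0.06 to 6.80 ± 0.31, Spred1 from 11.01 ± 0.04 to 8.25 ± 0.15, and Spry2 from 8.37 ± 0.10 to 5.85 ± 0.11, just below the background level. Myc fell from 10.66 ± 0.17 to 8.99 ± 0.24 and Fos from 13.43 ± 0.03 to 12.62 ± 0.23, while Jun, at 10.92 ± 0.11 and 10.83 ± 0.09, did not pass the test (adjusted p = 0.513).

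**Figure D2:**
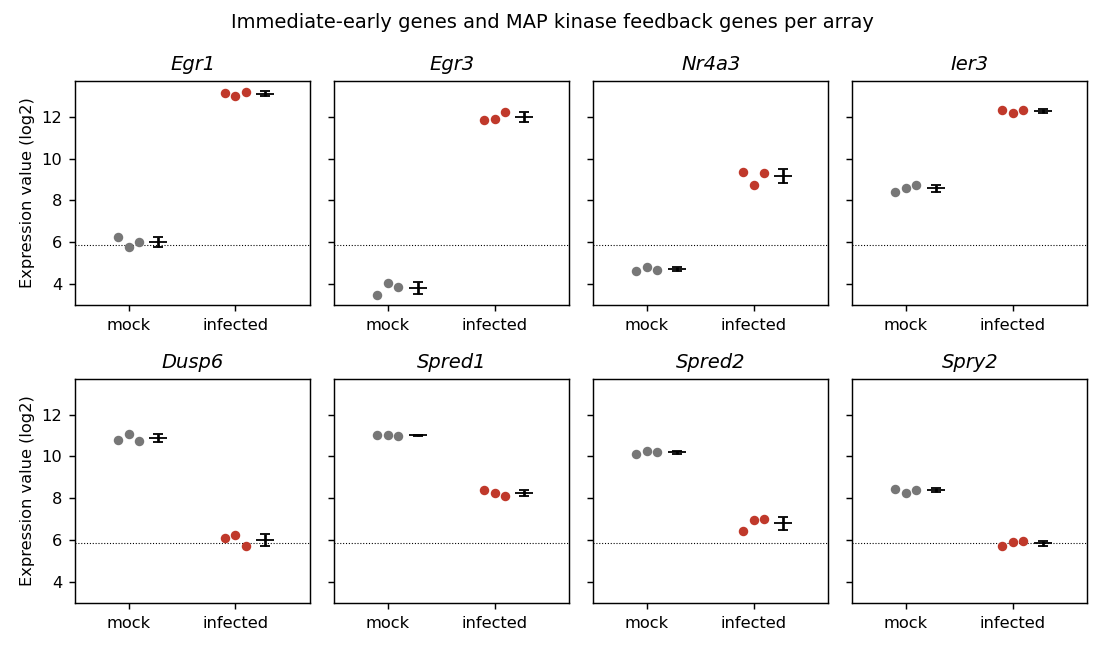
Log2 expression values of 8 genes of the immediate-early and MAP kinase feedback list; grey points are the 3 mock arrays, red points the 3 infected arrays, bars the mean and SD of each group, and the dotted line is the background level of 5.86. The upper row (Egr1, Egr3, Nr4a3, Ier3) is higher and the lower row (Dusp6, Spred1, Spred2, Spry2) lower in every infected array than in every mock array.

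Most STAT6 and alternative activation genes rose, with 16 of 22 higher, 2 lower and 4 not past the test (18 and 2 adjusted over the list alone). Arg1, Irf4 and Pdcd1lg2, the gene of the inhibitory ligand PD-L2, were among its members that rose, and Chil3 rose from 6.55 ± 0.22 to 10.01 ± 0.04 (SD, n = 3). Mrc1, the mannose receptor gene, rose by 1.32 ± 0.10 (± SE), whereas Msr1, a scavenger receptor gene, fell by 1.15. Retnla, another marker of this state, lay under the background level in both groups, at 4.38 ± 0.09 and 4.59 ± 0.11. The list passed camera's test at adjusted p = 6.22e-15, and had adjusted p = 0.0535 with an estimated correlation.

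Of the 21 STAT3 and SOCS genes, 16 rose and 3 fell, with the same counts adjusted over the list alone. Nfil3 rose from 6.00 ± 0.11 to 10.53 ± 0.11, and of the feedback inhibitors Socs3 rose by 3.95 ± 0.11 on the log2 scale (± SE) and Socs1 at least 4.43-fold, from below background. Stat3 itself rose by 1.17, while Bcl6 fell by 1.52 and Bcl2l1 by 1.95. This was the only list past the threshold both with the preset correlation (adjusted p = 1.03e-12) and with an estimated correlation (adjusted p = 0.0461). Its margin was small, since several other lists had adjusted p = 0.0535 with an estimated correlation. The cytokine, hypoxia and apoptosis lists missed with estimates of -0.020, -0.022 and -0.028, below the preset 0.01. Correlation between genes therefore does not explain why those lists missed.

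Arginine and polyamine genes were measured by 10 members, of which 6 rose and 1 fell, also when adjusted over the list alone. Arg2, the mitochondrial arginase, rose from 5.10 ± 0.17 to 10.87 ± 0.05, and the arginine transporter genes Slc7a2 and Slc7a1 rose by 3.20 ± 0.09 and 1.33 ± 0.09. Nos2, the inducible nitric oxide synthase that shares arginine as a substrate, lay under the background level at 4.84 ± 0.18 and 4.60 ± 0.16. The list's adjusted p was 0.000177, and adjusted p = 0.216 with an estimated correlation. It also missed the threshold with camera on ranks (adjusted p = 0.0663), and its adjusted p ranged from 3.27e-05 to 0.216 over the alternatives.

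NF-kB subunit and feedback genes were higher for 16 of 20 members and lower for 2 (17 and 2 adjusted over the list alone; adjusted p = 5.68e-12, and adjusted p = 0.0535 with an estimated correlation). Cd83 rose from 8.45 ± 0.06 to 13.37 ± 0.11, and the subunit genes Rel and Relb rose by 2.75 ± 0.10 and 1.91 ± 0.08 (± SE). The cytokine and growth factor list held 11 rises and 4 falls among 22 members (12 and 5 adjusted over the list alone; adjusted p = 3.79e-05, and adjusted p = 0.0535 with an estimated correlation). Csf1, Il1b and Osm rose by 4.28, 4.20 and 3.92, and Il1rn, the interleukin-1 receptor antagonist, rose from 9.81 ± 0.16 to 13.08 ± 0.17 (SD, n = 3). In the opposite direction, Tnf fell from 9.44 ± 0.12 to 8.16 ± 0.18 and Il10 fell at least 1.07-fold, to below the background level. Il12b and Il6 passed as higher but lay under that level in both groups.

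Chemokine genes rose in 13 of 22 cases and fell in 3 (15 and 5 adjusted over the list alone; adjusted p = 1.11e-05, and adjusted p = 0.129 with an estimated correlation). Ccl24, an eosinophil attractant, reached 11.18 ± 0.21 from 5.55 ± 0.23, and the neutrophil attractant Cxcl2 rose by 3.27. Monocyte attractants moved apart, with Ccl12 from 8.58 ± 0.12 to 5.36 ± 0.40 and Ccl2 from 10.49 ± 0.08 to 9.75 ± 0.12 lower, Ccl7 higher by 0.90 ± 0.12, and Ccl8 at 8.56 ± 0.06 and 8.34 ± 0.08 not past the test (adjusted p = 0.0607). Among 13 costimulation and checkpoint genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 9.93e-06, and adjusted p = 0.0535 with an estimated correlation). Cd274, the gene of PD-L1, rose from 7.04 ± 0.20 to 11.23 ± 0.09, and Cd86 from 9.30 ± 0.13 to 11.74 ± 0.16.

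**Figure D3:**
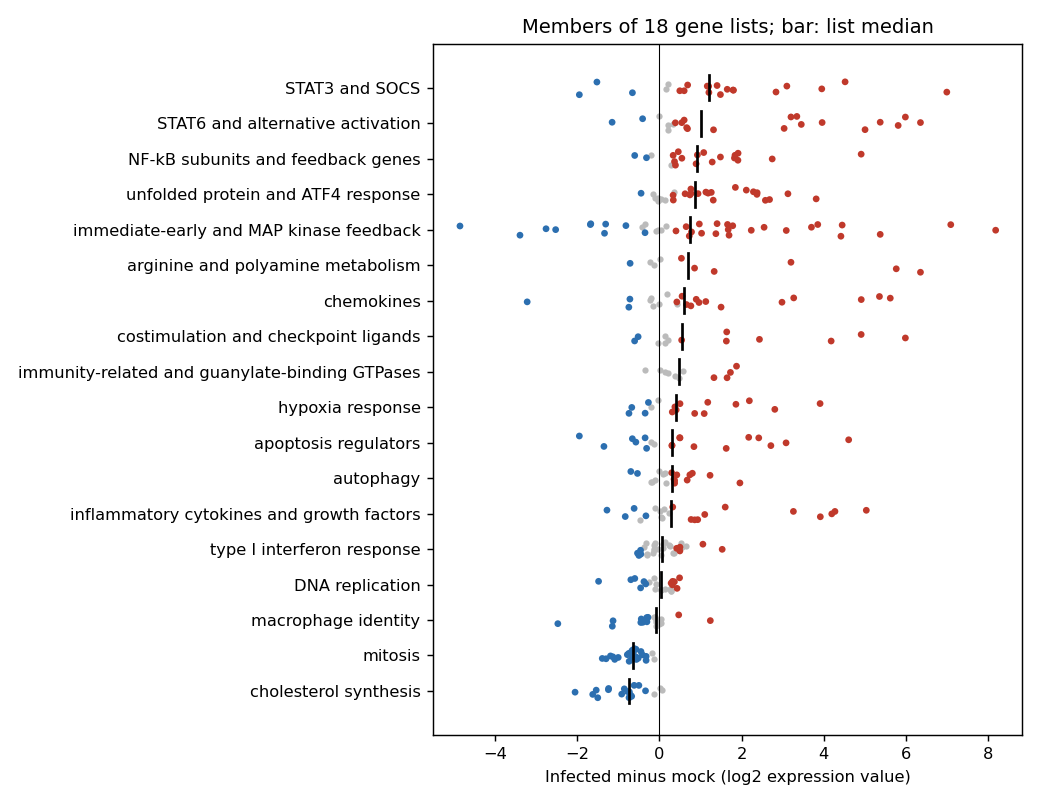
Log2 change (infected minus mock) of every measured member of the 16 gene lists that passed camera's test with the preset correlation, and of the type I interferon response and DNA replication lists; red members were higher, blue lower and grey not past adjusted p = 0.05, and black bars are list medians. The differences are not bounded at background, and the medians run from -0.74 for cholesterol synthesis to 1.20 for STAT3 and SOCS.

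The unfolded protein and ATF4 list had 20 of 28 members higher and 1 lower, also when adjusted over the list alone (adjusted p = 5.83e-15, and adjusted p = 0.0535 with an estimated correlation). Trib3 and Ddit3 rose by 3.82 ± 0.10 and 2.12 ± 0.07 on the log2 scale (± SE), Chac1, which degrades glutathione, by 3.13 ± 0.12, the serine synthesis gene Phgdh by 2.68 ± 0.09, Herpud1, which acts in the degradation of proteins of the endoplasmic reticulum, by 2.58 ± 0.09, and the cystine transporter gene Slc7a11 by 2.38 ± 0.13. Among chaperone genes of the endoplasmic reticulum Dnajb9 rose by 1.26 ± 0.09, Creld2 fell by 0.45, and Hspa5 (0.14 ± 0.07), Hsp90b1 (-0.04 ± 0.12) and Calr (0.04 ± 0.07) did not pass the test. Hypoxia response genes rose in 11 of 17 cases and fell in 4, also when adjusted over the list alone (adjusted p = 0.000215, and adjusted p = 0.0546 with an estimated correlation), with Adm at least 9.72-fold higher, from below background, Ndrg1 higher by 2.81 ± 0.10, while Car9 fell by 0.74. Autophagy genes rose in 10 of 19 cases and fell in 2, also when adjusted over the list alone, led by Gabarapl1 and Uvrag (1.96 ± 0.11 and 1.23 ± 0.07). The autophagy list's adjusted p was 0.00277, and adjusted p = 0.135 with an estimated correlation.

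Of 19 apoptosis regulators 11 rose and 6 fell (11 and 7 adjusted over the list alone). Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from 7.36 ± 0.46 to 11.97 ± 0.24, and Gadd45b and Fas rose by 3.08 and 2.42. Both the anti-apoptotic Bcl2l1 and the pro-apoptotic Bid fell, by 1.95 ± 0.10 and 1.35 ± 0.07. The list had adjusted p = 0.0176, and adjusted p = 0.135 with an estimated correlation. It also missed the threshold when only genes brighter than background were tested (adjusted p = 0.146) and with camera on ranks (adjusted p = 0.292), with a range from 1.89e-05 to 0.292 over the alternatives.

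Cholesterol synthesis genes fell in 17 of 20 cases and none rose, also when adjusted over the list alone (adjusted p = 3.72e-11, and adjusted p = 0.0535 with an estimated correlation). Hsd17b7 fell from 10.26 ± 0.18 to 8.20 ± 0.15, Msmo1 from 12.09 ± 0.26 to 10.46 ± 0.08, Sqle, which encodes squalene epoxidase, from 11.68 ± 0.02 to 10.14 ± 0.06, and Fdft1 from 10.94 ± 0.05 to 9.44 ± 0.03. Srebf2, the gene of the transcription factor that drives this pathway, fell by 0.62 ± 0.08. Among 14 LXR target and lipid efflux genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; adjusted p = 0.151). The list passed as lower with values under background raised to it (adjusted p = 0.0459), in a range from 0.000828 to 0.373 over the alternatives. It did not pass when only genes above background were tested (adjusted p = 0.202). Abcg1 and Abca1, which export cholesterol, rose by 1.68 ± 0.11 and 0.73 ± 0.09, and the desaturase gene Scd2 fell by 2.31 ± 0.10.

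Mitosis genes fell in 22 of 24 cases and none rose (23 lower adjusted over the list alone), with a median of -0.64. Aurka, Prc1, Kif23 and Plk1 fell by 1.39, 1.30, 1.19 and 1.13. The list passed with the preset correlation (adjusted p = 2.07e-12) but had adjusted p = 0.216 with an estimated correlation. DNA replication genes were split, with 7 of 23 higher and 6 lower (8 and 7 adjusted over the list alone; adjusted p = 0.669). Mcm2 and Mcm6 of the replicative helicase rose by 0.43 ± 0.10 and 0.32 ± 0.08, whereas Cdc6, which loads that helicase, fell from 8.59 ± 0.09 to 7.11 ± 0.06. Neutrophils are another cell type that marrow cultures can hold, and some of their markers were lower in the same infected arrays. Of 13 measured, S100a9, S100a8, Ngp, Ltf and Lcn2 were lower, S100a9 from 8.24 ± 0.16 to 6.73 ± 0.06, and Csf3r was higher by 1.85 ± 0.11 (1 and 5 also adjusted over the list alone; adjusted p = 0.0613). The list passed as lower without mock replicate 1 (adjusted p = 0.0224) or infected replicate 2 (adjusted p = 0.0481), in a range from 0.0104 to 0.373 over the alternatives.

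**Figure D4:**
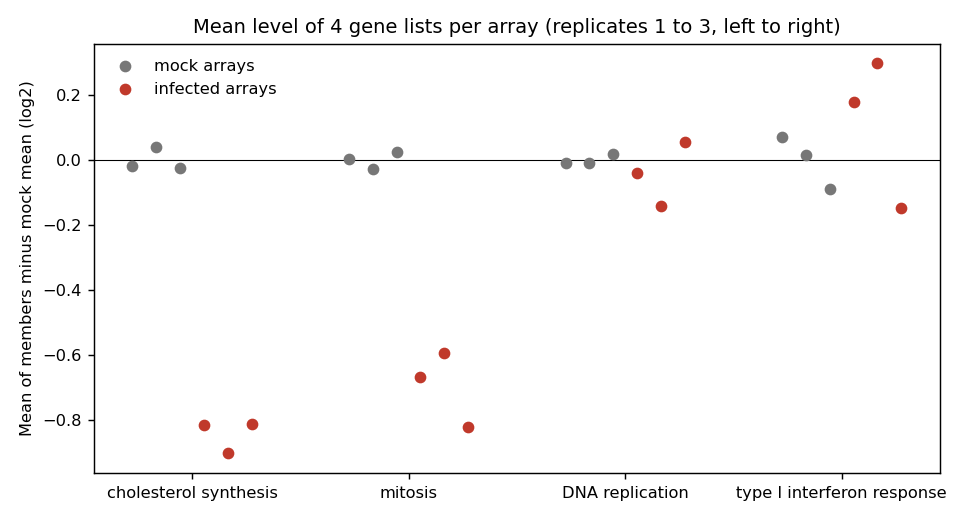
Mean level of 4 gene lists on each array relative to the mean of the 3 mock arrays (log2, vertical axis), with grey points for mock and red points for infected replicates 1 to 3 from left to right. Cholesterol synthesis and mitosis lie below all mock arrays in each infected array, and the type I interferon response lies at 0.18 and 0.30 in infected replicates 1 and 2 and at -0.15 in replicate 3.

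The type I interferon response was not shifted as a list. Of 30 genes 5 rose, 4 fell and 21 did not pass the test (8 and 6 adjusted over the list alone; adjusted p = 0.446). Usp18 and Mx1 rose by 1.53 ± 0.14 and 1.06 ± 0.15, and Ifit1 stood at 8.84 ± 0.49 and 9.07 ± 0.60 (adjusted p = 0.624). Without infected replicate 3, where 28 of the 30 genes were lower than in both other infected arrays, the list passed as higher (adjusted p = 0.027, in a range from 0.027 to 0.877 over the alternatives). Of 11 immunity-related and guanylate-binding GTPase genes, whose proteins attack the parasite's vacuole, 4 rose and none fell (5 higher adjusted over the list alone). Gbp7, Gbp3 and Gbp2 rose by 1.88 ± 0.10, 1.73 ± 0.10 and 1.65 ± 0.11, and Gbp8 rose below the background level. Irgm1 (-0.34 ± 0.16) and Igtp (0.13 ± 0.13) did not pass. The list had adjusted p = 0.00019, and adjusted p = 0.258 with an estimated correlation. Its mean stood at 0.81, 0.89 and 0.49 above mock in infected replicates 1, 2 and 3, and without replicate 3 its adjusted p was 1.47e-06, in a range from 1.47e-06 to 0.258 over the alternatives.

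Most antigen presentation genes did not pass the test by limma. Tap1, a peptide transporter gene, rose from 8.93 ± 0.05 to 10.29 ± 0.09 together with Psmb9 and Tapbp, which made 3 of 12 class I genes higher and none lower, also when adjusted over the list alone (adjusted p = 0.0623). The class I list passed without mock replicate 1 (adjusted p = 0.0389) or infected replicate 3 (adjusted p = 0.039), in a range from 0.00574 to 0.339. It also passed with values under background raised to it (0.0267), though not when only genes above background were tested (0.161). The mean of all probe sets (0.0473) and no _x_at or _s_at probe sets (0.0316) let it pass. Limma's trend and robust settings (0.0381), array weights (0.0306) and fry (0.00574) let it pass too. The call on Tapbp ended without infected replicate 2 (adjusted p = 0.0722, in a range from 0.00365 to 0.0779). Among 12 class II genes H2-Eb1 alone passed and fell by 0.23, at adjusted p = 0.0385, and none was adjusted over the list alone (list adjusted p = 0.652). This call on H2-Eb1 ended when any single array was left out (adjusted p between 0.0579 and 0.109, against 0.00367 to 0.109 over all alternatives). Of 25 pattern recognition genes 4 rose and 10 fell (4 and 11 adjusted over the list alone; adjusted p = 0.192). Casp4, which senses cytosolic lipopolysaccharide, rose by 1.76 ± 0.08 and Tlr4 by 1.56 ± 0.08, while Tlr13 and Tlr1 fell by 1.63 and 0.95.

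Macrophage identity genes did not move as a block, in the arrays where the neutrophil markers S100a8 and S100a9 fell by 1.26 and 1.52. Csf1r stood at 14.15 ± 0.04 and 14.12 ± 0.01 and Lyz2 at 14.62 ± 0.01 and 14.61 ± 0.02, while Cx3cr1 fell from 11.46 ± 0.08 to 8.99 ± 0.29 and Maf and Fcgr1 fell by 1.15 ± 0.11 and 1.13 ± 0.10. The levels of Csf1r and Lyz2 lie close to the array maximum of 14.8, which leaves little room for a rise to show. Of 24 members 2 rose and 9 fell (2 and 10 adjusted over the list alone; adjusted p = 0.0483, and adjusted p = 0.585 with an estimated correlation). That call was near the threshold and ended without mock replicate 2 (adjusted p = 0.122) or without infected replicate 3 (adjusted p = 0.0743), in a range from 0.00214 to 0.585 over the alternatives. It also ended with centring on the housekeeping list (0.0558), array weights (0.0651), the mean of all probe sets (0.123) and no _x_at or _s_at probe sets (0.0876). Testing only genes above the median (0.122) or above background (0.0862) ended it too. Chemokine receptor and adhesion genes rose in 2 of 16 cases and fell in 8 (3 and 9 adjusted over the list alone; adjusted p = 0.091), with Ccrl2 higher by 2.55 ± 0.11, while Ccr1 and the integrin gene Itga5 fell by 1.38 and 1.17. With values under background raised to it this list passed as lower (adjusted p = 0.0159), in a range from 0.00836 to 0.523 over the alternatives. It did not pass when only genes above background were tested (adjusted p = 0.118). In matrix proteolysis 6 of 18 genes rose and 4 fell (6 and 5 adjusted over the list alone; adjusted p = 0.567). The protease inhibitor gene Timp1 rose by 3.59 ± 0.11 and Plau, the urokinase gene, fell at least 1.67-fold, to below background.

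Glycolysis genes rose in 5 of 18 cases and fell in 4 (5 and 5 adjusted over the list alone; adjusted p = 0.498), with the glucose transporter gene Slc2a1 higher by 1.22 ± 0.10, while Hk1 fell by 0.87 ± 0.08. In oxidative phosphorylation 1 of 25 genes rose and 2 fell (adjusted p = 0.132), in the lysosome list 1 of 25 rose and 3 fell (adjusted p = 0.669), both with the same counts adjusted over the list alone, and in ribosome biogenesis 5 of 26 rose and 3 fell (5 and 5 adjusted over the list alone; adjusted p = 0.98). The NRF2 and metal response list had 2 of 14 genes higher and 7 lower (2 and 8 adjusted over the list alone; adjusted p = 0.091). Its metallothionein gene Mt2 rose by 1.38 ± 0.11 and Hmox1, heme oxygenase 1, fell from 11.09 ± 0.13 to 9.87 ± 0.39. In eicosanoid synthesis 2 of 12 genes rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p = 0.091). The prostaglandin receptor gene Ptger2 rose by 2.17 ± 0.12 and Pla2g4a, cytosolic phospholipase A2, fell by 2.04 ± 0.08. With values under background raised to it, oxidative phosphorylation, NRF2 and eicosanoid genes passed as lower (adjusted p = 0.00214, 0.0241 and 0.0179). That setting holds dim comparison genes at a change near 0. Oxidative phosphorylation and NRF2 had 0 members below background, so mainly the genes they were compared with changed. When only genes above background were tested, these lists missed the threshold (adjusted p = 0.161, 0.161 and 0.165). Over all alternatives their adjusted p ranged from 0.00214 to 0.6, from 0.00129 to 0.282 and from 5.55e-05 to 0.258.

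Markers of other cell types changed in few cases, and none of their 8 lists passed camera's main test. Ppbp, a platelet chemokine gene, rose from 7.64 ± 0.09 to 11.21 ± 0.16 as the only 1 of 9 erythroid and platelet markers (adjusted p = 0.669), while Pf4 stood at 12.53 ± 0.04 and 12.61 ± 0.06. Zbtb46 was the only 1 of 10 dendritic cell markers to rise, at least 2.21-fold from below background (list adjusted p = 0.498). Among 10 endothelial markers Kdr fell by 0.91 ± 0.12, while Pecam1 was higher and Cdh5 and Emcn lower, all 3 below the background level in both groups (adjusted p = 0.455). Of 13 T and NK cell markers Prf1 rose and Cd5 fell, both below background (adjusted p = 0.669), and of 9 B cell markers Ighm fell by 0.38 ± 0.10 (adjusted p = 0.906). The call on Prf1 ended without mock replicate 2 or infected replicate 2 (adjusted p = 0.0556 and 0.057, in a range from 0.00759 to 0.296), and that on Ighm without infected replicate 3 (adjusted p = 0.0654, in a range from 0.00663 to 0.327). No member of the mast cell and eosinophil list (13 measured; adjusted p = 0.513) or of the fibroblast and stromal list (14 measured; adjusted p = 0.9) passed by limma. The counts of these 7 lists were the same adjusted over the list alone. For glycolysis, DNA replication, lysosome, erythroid and platelet, and fibroblast and stromal genes the list's median, mean and test differed in sign, and none of these lists passed camera's main test. By fry, glycolysis (adjusted p = 0.0233), erythroid and platelet (0.00857), dendritic cell (0.00574) and matrix proteolysis (0.0342) genes passed as higher. Mast cell and eosinophil (0.0453) and class II (0.0453) genes passed by fry as lower.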

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

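The main test used probe sets with a single gene symbol. Probe sets outside it also carried a difference between infected and mock arrays. When all 45037 probe sets other than controls were tested by limma, 545 of the probe sets with no gene symbol were higher and 657 lower in infected macrophages, and 122 and 97 of them changed at least 2-fold. By the differences of the group means, the largest rise among them went from 4.58 ± 0.63 to 10.49 ± 0.13 (SD, n = 3) and the largest fall from 8.63 ± 0.04 to 6.30 ± 0.16. The mock level of that rise lay under background, so its size and rank are uncertain. Of the probe sets with several symbols 77 were higher and 87 lower. Their genes were not named here.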

How the results depend on the processing

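All alternatives below were planned except the splitting of the unfolded protein and ATF4 list, chosen after seeing the data. The counts of genes higher in infected, genes lower in infected, genes at least 2-fold higher in infected and genes at least 2-fold lower in infected stayed within 1.5 times of 2172, 2492, 502 and 295 except with every probe set as a feature, which gave 4165, 5011, 1005 and 657 because more features were tested. Leaving out each array in turn gave 1756 to 2105, 1818 to 2372, 476 to 529 and 264 to 338; without mock replicate 1, whose BioB and BioC hybridisation controls were the highest, the counts were 2105, 2372, 502 and 317. Centring on the housekeeping list lowered the share of higher genes among calls from 46.6% to 39.5%.

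The fixed gene lists past the threshold numbered 16, 15 to 18 without single arrays, 21 (13 higher, 8 lower) with values under background raised to it, 16 with the unfolded protein and ATF4 list given as 2 parts, 1 with an estimated correlation and 29 by fry, which asks another question. Raising values to background holds dim genes near a change of 0, which alters what camera compares a list with. When only genes above background were tested, 14 lists passed. Of 139 named genes past the threshold, 126 stayed past it, in the same direction, in every alternative that gave a value. Ak4 lost its call without probe sets ending in _x_at or _s_at, with a change of -0.20 that did not pass (adjusted p = 0.106, in a range from 1.61e-06 to 0.106); the cause was not tested. Raising values to the background level left no value for genes dim in all arrays, such as Ddx4 and Gbp8.

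Some lists changed direction without passing, with these adjusted p; ranges cover all 6 fits that leave out an array, not all of which turned. Ribosome biogenesis turned with centring on the housekeeping list (0.988), without _x_at and _s_at probe sets (0.997), with trend and robust settings (0.955), with array weights (0.973) and without mock replicate 2, infected replicate 1 or infected replicate 2 (range 0.464 to 0.964). DNA replication turned by fry (0.338) and without infected replicate 3 (range 0.336 to 0.949). B cell markers turned with values raised to background (0.994), with the mean of all probe sets (0.779) and without mock replicate 1 or infected replicate 3 (range 0.678 to 0.984). Dendritic cell markers turned among genes above the median (0.707), and mast cell and eosinophil markers with values raised to background (0.994). Fibroblast and stromal markers turned with values raised to background (0.972), among genes above background (0.681), by fry (0.762) and without mock replicate 3 or infected replicate 3 (range 0.678 to 0.949). The causes were not tested.

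Same-numbered mock and infected arrays deviated from their group means with correlations of 0.20, 0.11 and 0.04. Infected replicates 1 and 2 correlated best with the mock array of their own number, and infected replicate 3 with mock replicate 2 (0.06). Such small values from 3 arrays per group cannot settle a pairing. The numbers were not taken to pair the samples, and pairing stays open. With the replicate block the counts were 2284, 2591, 502 and 295, with 16 lists, and among named genes the block ended the call on H2-Eb1 alone (adjusted p = 0.0583).

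The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4664 genes, 797 of them at least 2-fold changed, and the highest of the other splits called 0 of either; it called 16 lists and the highest other split 13. In each case 1 split, the real one, reached the real value. Every other split has arrays of both groups on each side, so the infection difference adds to its spread and low gene counts follow from the splitting itself. Part of that difference also remains between its sides, so the counts of the other splits do not measure chance. Signal near background limits what can be said of dim genes, since 10387 of 18193 genes had a group mean above it.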

Other observations

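The tests of infected replicate 3, the families by symbol root and the division of the unfolded protein and ATF4 list were chosen only after the results were seen. The genes named here outside the fixed lists were chosen after their values were seen. The tests on the EGR, NR4A and MAP kinase feedback genes and on Ddx4 address patterns already seen in the gene results.

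Genes outside the fixed lists also changed strongly. Those higher in infected macrophages included Ahr, the aryl hydrocarbon receptor gene, Rasgrp1, which encodes an activator of Ras, the transcription factor genes Bhlhe40, Batf3 and Prdm1, and Fcgr2b, the inhibitory Fc receptor gene. Among those lower were Jag1, a Notch ligand gene, Ch25h, which makes 25-hydroxycholesterol, Il17ra, C5ar1 and the kinase genes Pik3cg and Ptk2b. The heat shock genes Hspa1b and Hspa1a rose, from 7.56 ± 0.06 to 9.18 ± 0.19 and from 6.43 ± 0.15 to 7.54 ± 0.19 (SD, n = 3), while Hspa8 (0.06 ± 0.08) and Hspa4 (0.25 ± 0.11; ± SE) did not pass. The Hspa family as a whole, with 6 of 10 members higher and none lower, missed the threshold (camera adjusted p = 0.0606, and adjusted p = 0.894 with an estimated correlation). It was among 161 families of at least 8 genes with a shared symbol root, none of which passed.

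The members of the unfolded protein and ATF4 list moved unevenly. Of the 8 chaperones and folding enzymes of the endoplasmic reticulum, Dnajb9 rose, Creld2 fell and 6 did not pass the test. Of the other 20 members 19 rose and none fell. The division was made after these values were seen, and no test compared its parts.

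EGR and NR4A genes rose while Dusp6, Dusp4, Spry2, Spred1 and Spred2 fell, although both groups are known targets of ERK signalling, and among other phosphatase genes of the list Dusp2, Dusp5, Dusp14 and Dusp16 rose. The choice of probe set is argued against, since 0% of the 16 other probe sets of these genes above background changed in the opposite direction and 12 changed in the same one. Egr1 and Dusp6 have a single probe set, so this does not cover them. Lower ERK output is a candidate explanation of the falls alone. Of 6 further ERK output genes above background 3 fell (Dusp7, Spred3 and Epha2) and 1 rose (Rasgef1b), and their median change of -0.47 stood at percentile 0.23 of 10000 random lists matched on mean level. Dusp7 and Spred3 belong to the gene families of Dusp6 and of Spred1 and Spred2, whose falls were already seen. The random lists did not match family membership, so this percentile is not independent support. Lower ERK output would leave the rise of EGR and NR4A genes and of Dusp2, Dusp5, Dusp14 and Dusp16 unexplained, the list is short, and ERK activity was not measured.

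Ddx4, a germ cell gene of the tissue-restricted list, rose from 3.45 ± 0.12 to 5.26 ± 0.09, below the background level. Il6st, Il31ra, Ddx4 and Slc38a9 follow each other on chromosome 13, and all were higher in infected macrophages, Il6st by 1.80, Slc38a9 by 1.42 and Il31ra at least 1.71-fold, from below background (difference of the means 1.10), so transcription spreading around an induced neighbour may contribute. More widely, 28.8% of 111 genes next to a gene that rose at least 8-fold were higher, against a median of 11.7% and a 95th percentile of 17.1% in 10000 random draws matched on mean level. The draws did not match the clustering of related genes under other names, and shared regulation and read-through were not told apart. Parasite RNA binding to mouse probe sets stays open, since dim genes of conserved families were higher in 5.81% of cases and other dim genes in 4.60% (odds ratio 1.28, one-sided Fisher's exact p = 0.288). Ddx4 itself is one of the 9 of 155 conserved dim genes counted as higher.

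Interferon response genes were lower in infected replicate 3, by a median of 0.37 on the log2 scale, in 28 of 30 genes. The 192 risers of the other lists were not lower there as a set, with a median difference of 0.047. They were called higher with that array included, which favours genes that rose in it. Less complete infection of that culture therefore stays open. The 10 housekeeping genes differed by a median of 0.00029 (-0.040 to 0.12). Quantile normalization removes a shift of the whole array beforehand, so these values cannot test for one. No other biological explanation was tested, and a difference between cultures in interferon signalling also stays open.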
